A study of Mus musculus with 8 samples.

How the data were processed

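The study profiled heart cells of mouse embryos at embryonic day 10.5 that carried a minK-GFP bacterial artificial chromosome, in which green fluorescent protein reports the activity of minK (Kcne1), a potassium channel subunit. Per the labels' protocols, hearts were dissociated with enzymes and the cells were sorted by fluorescence into a GFP-high group, described as cardiac conduction system cells, and a GFP-low group, described as chamber myocardium. Each group had 4 samples that the labels call biological replicates, so 8 arrays were compared. From each sample 5 ng of RNA was amplified and 2 ug of the product was labelled with 1 dye, so levels of dim genes also carry the spread of the amplification.

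The deposited files are 1-colour Agilent scanner outputs and hold spot intensities on a linear scale. Per the submitters' processing notes and the file headers, the images were read with Agilent Feature Extraction version 10.5.1.1, which subtracted background, removed spatial and multiplicative trends and replaced the lowest values by surrogates before the authors deposited them. Between 34.8% and 49.4% of the non-control spots of an array held a surrogate value. Each array had 43379 non-control spots and 1639 control spots, and no spot was saturated. The whole-series table deposited by the authors held the same intensity in all 45018 spots of each array, unscaled and uncentred, so its use as a source of values gave identical results; its column medians ran from 12.2 to 19.9. Flags of the scanner software marked which spots were well above background and which were outliers. Scan and slide coincided: slide 1 held replicates 1 and 2 of both groups and slide 2 held replicates 3 and 4 of both groups.

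Log2 of the processed signal minus each array's 75th percentile over non-control spots was used throughout, with R 4.3.3 and limma 3.58.1. Control spots and spots flagged as outliers were left out, and spots of 1 probe were averaged. Of 41174 non-control probes, 33096 received a current symbol from the reference gene table of assembly GRCm38.p6, which was used for names only; other probes kept the name in the files. The probe with the highest mean signal over the 8 arrays stood for each of 27827 gene names. A gene was tested if this probe was well above background on at least 4 of the 8 arrays, which left 12889 genes and left out 14938. Among 4228 tested genes with 2 or more measured probes, 1328 had probes of opposite sign, so a single probe's difference is not always shared by its gene. Probe coordinates are those of the files, on mouse build mm9.

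GFP-high was compared with GFP-low by lmFit and eBayes, with the group as the only term and Benjamini-Hochberg adjusted p under 0.05. Differences are log2 of GFP-high over GFP-low, with the standard error of the fit. The median difference of all tested genes was 0.16, and it lay between 0.05 and 0.10 under the other scalings and background corrections, so relative to the median gene a rise is smaller and a fall larger by that amount. Where no array of 1 group measured a probe above background, the fold is given as a lower bound: the mean of the brighter group against the mean of the dimmer group in which each array's value was raised to its lowest signal well above background. The fit was tested on simulated arrays with the means and spreads of the 12889 genes and 200 changed genes. It recovered 1.4% of the genes changed by 1 on the log2 scale and 39.0% of those changed by 2, with 7.13% of the calls false, and all true calls had the right direction. Small changes were therefore mostly out of reach of 4 arrays per group. The set test found a simulated list of 20 genes shifted by 1 in 10 of 10 runs. The simulated genes were drawn independently of each other. The sarcomere, glycolysis and ribosomal lists described below had estimated correlations of 0.49, 0.57 and 0.68, and smaller medians. These runs therefore do not show how the set test behaves on such lists.

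Before the data were examined, 24 gene lists were fixed from textbook knowledge: heart regions and functions, other cell types that the sort could hold, and sample handling. They were tested with camera at a preset correlation of 0.01, and beside it with camera at an estimated correlation, fry and an exact two-sided permutation of the list mean over the 70 assignments of the arrays, for which the smallest possible p is 0.0286. The ion channel and ribosomal lists took every tested gene with their prefixes, so the ribosomal list also held 6 kinases of ribosomal protein S6. The named genes followed a rule fixed at the same time: the reporter gene and established conduction and chamber genes; the 10 largest called differences per direction with separated arrays, measured on all arrays of the higher group and at least 1 of the other; the 5 largest bounds per direction; and for each list the 3 largest called members per direction or, without one, the 2 with the smallest p. The values of 2 genes that the rule names are not reported here. Genes named outside this rule are said to have been chosen after their values were seen.

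The alternatives fixed in advance were quantile normalisation, scaling to the median of detected spots, normexp background correction with an offset of 50 under both scalings, 3 other filters on dim probes, the mean over probes, the values of the whole-series table, eBayes with trend and robust fitting, array weights, the replicate number as a block, the slide as a block, each array left out in turn, a threshold of 0.01 and the other set tests. A block for scan date was not run, since all scans shared a day. A percentile over detected spots, a common floor, a correction for probe GC content with and without the replicate block, a threshold of 0.1 and values within slides were added after seeing the data. The p-values measure the spread between the sorted samples; the labels do not say whether equal replicate numbers mark 1 litter or sort. The number of arrays limits the precision of all values.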

Results

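The arrays measured RNA from 4 GFP-high and 4 GFP-low sorted samples of E10.5 mouse hearts. Between 15735 (GFP-high replicate 3, 36.3%) and 22003 (GFP-low replicate 2, 50.7%) non-control spots were well above background. The number did not separate the groups: the mean was 19100 ± 2543 (SD, n = 4) in GFP-high and 19640 ± 1841 (SD, n = 4) in GFP-low (exact two-sided permutation test, p = 0.743). Correlations between arrays across tested genes ran from 0.869 to 0.921 within GFP-high, from 0.893 to 0.929 within GFP-low and from 0.820 to 0.928 between the groups.

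Kcne1, the gene whose regulatory region drives the reporter, was examined first because it checks the sort. It was higher in all 4 GFP-high arrays than in every GFP-low array on both of its probes. The brighter probe (mm9 chromosome 16, 92346251 to 92346310) read 1.67 ± 0.57 in GFP-high and 0.37 ± 0.39 in GFP-low on the log2 scale (SD, n = 4 each), a 2.45-fold difference. The other probe (chromosome 16, 92348745 to 92348804) gave 2.24 ± 0.38 and -0.60 ± 0.28, a 7.13-fold difference. The exact permutation p was 0.0286 for each, the smallest that 4 against 4 arrays can give. On the log2 scale the brighter probe differed by 1.42 within slide 1 and 1.17 within slide 2. In the model over all genes the brighter probe had a limma adjusted p of 0.201, and averaging both probes gave 0.0394. As the cells were sorted on this reporter, its difference is a check of the labels and not a finding.

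The comparison of the groups asks which genes distinguish cells labelled as conduction system from those labelled as chamber myocardium. In GFP-high, 9 genes rose. They included Gal, which encodes the neuropeptide galanin, Eno2, the neuronal enolase, Pcsk6, a proprotein convertase, Cacna2d2, an accessory subunit of voltage-gated calcium channels, and Gpc1, a cell surface proteoglycan. In GFP-high, 9 other genes fell, among them Ccne2, which encodes cyclin E2, the matricellular gene Smoc2, the guidance factor Sema3a and Mab21l2. Each of the 18 differed by at least 2-fold.

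Of the genes measured above background in both groups, Gal had the largest rise, 3.55 ± 0.47 on the log2 scale (SE, 11.7-fold, limma adjusted p = 0.0447; chromosome 19, 3411143 to 3411202). Eno2 rose by 2.50 ± 0.32 (5.66-fold), and its second probe gave 2.47. Pcsk6 rose by 2.09 ± 0.27 (4.24-fold), Gstm7, a glutathione S-transferase, by 1.93 ± 0.23 (3.82-fold), Cacna2d2 by 1.87 ± 0.26 (3.66-fold) and Gpc1 by 1.64 ± 0.22 (3.12-fold). The 3 other probes of Cacna2d2 gave 1.67, 1.02 and 1.67, but the mean over its probes did not pass (1.56, limma adjusted p 0.0763). The rises from Gal to Gpc1 each passed in only 8 to 10 of 25 alternatives. With the slide as a block only Cacna2d2 of them passed (0.0390), and the others had adjusted p from 0.0516 to 0.0776. After a correction for probe GC content Gal (0.0571), Eno2 (0.0706) and Cacna2d2 (0.0870) did not pass, and the others did. Cacna2d2 lay at chromosome 9, 107429535 to 107429678, and Gpc1 at chromosome 1, 94756711 to 94756770. In 3 further genes no GFP-low array was well above background. The kinase gene Stk32b was at least 7.49-fold higher, the noncoding Lhx1os, called 1500016L03Rik in the files, at least 5.20-fold and Shroom1, an actin-binding gene, at least 3.29-fold. These bounds raise only the dimmer group, each array to its own limit. With a common floor, which raises all values near background on all arrays to the highest of these limits, the log2 differences were 1.78 for Stk32b, 1.26 for Lhx1os and 0.63 for Shroom1, and none of the 3 passed; with normexp background correction they were 2.05, 1.77 and 0.95, and Shroom1 did not pass.

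Ccne2 (chromosome 4, 11130171 to 11130230) fell by 4.00 ± 0.46 (SE, log2, limma adjusted p = 0.0447) and Mia2, an endoplasmic reticulum export gene, fell by 3.86 ± 0.54. Both were measured above background on 4 GFP-low arrays but on only 1 GFP-high array. Carnmt1, a methyltransferase gene, fell by 2.11 ± 0.28 (4.31-fold) and was measured on 3 GFP-high arrays. The sizes depend on how signals near background are treated: with normexp background correction Ccne2 fell by 1.79, Mia2 fell by 1.81 and Carnmt1 fell by 1.13, with the common floor Ccne2 fell by 2.36 and Mia2 fell by 2.27, and the mean over the probes of Mia2 fell by 1.77. Calls ended too: Mia2 did not pass in any of these 3 (adjusted p 0.0936, 0.0723 and 0.0763) and passed in only 3 of 24 alternatives, and Carnmt1 did not pass with normexp (0.108). In 6 genes no GFP-high array was well above background. Mab21l2 (chromosome 3, 86350281 to 86350340) was at least 5.87-fold lower, Smoc2 (chromosome 17, 14540516 to 14540575) at least 3.17-fold, Snx16 at least 2.83-fold, Sema3a (chromosome 5, 13599978 to 13600037) at least 2.76-fold and Csrnp3 at least 2.51-fold. A clone with no gene symbol, named here because it completes the count, was at least 3.96-fold lower. None of these 6 passed with the common floor, where Mab21l2 fell by 1.66, Smoc2 fell by 0.77, Snx16 fell by 0.61, Sema3a fell by 0.65 and Csrnp3 fell by 0.50 on the log2 scale. With normexp none passed either, and Smoc2 fell by 0.65 and Mab21l2 fell by 1.65.

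The 18 genes came from 12889 tested, with adjusted p from 0.0341 to 0.0494. At an unadjusted p under 0.05 there were 1847 genes, 1024 higher and 823 lower, where 644 would be expected for arrays that differ in nothing. The 2 groups' arrays did not overlap in 1154 genes, 9% of those tested against an expected 2.9%. Of the 35 divisions of the arrays into 4 and 4, 3 gave as many genes by either measure, the real one included. With the slide as a block 11 genes passed, 3 higher and 8 lower. With the replicate number as a block 0 genes passed (smallest limma adjusted p 0.134). The labels do not say whether equal numbers mark 1 litter or sort. Within slide 1 and within slide 2, with 2 arrays per group, 0 genes passed limma (1570 and 791 at an unadjusted p under 0.05). There the 18 genes stood at 0.717 to 1.28 times their pooled difference. Their arrays were separated, which fixes the sign. Each slide held 2 of the 4 arrays per group, so the 2 ratios of a gene balance around 1. The count rested on single arrays: it was 1, 7, 7 and 0 without GFP-high replicates 1 to 4, and 0, 0, 0 and 1 without GFP-low replicates 1 to 4, with 1250 to 2580 genes at an unadjusted limma p under 0.05 in these fits. With normexp background correction 14 genes were higher and 6 lower, and with normexp and quantile normalisation 12 and 3.

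**Figure D1:**
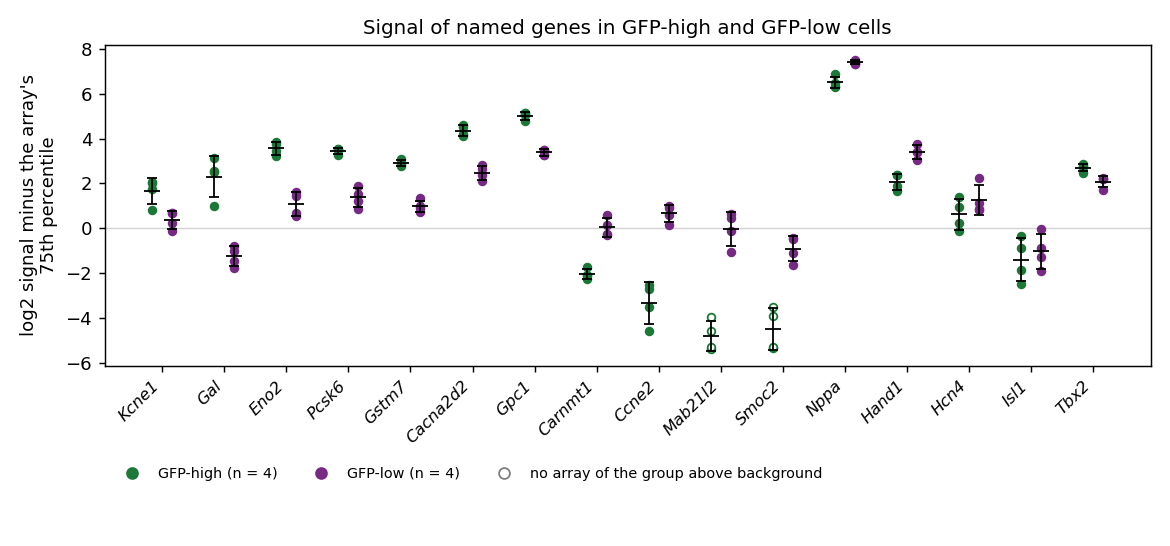
Log2 signal minus the array's 75th percentile for 16 genes on each of the 4 GFP-high (green) and 4 GFP-low (purple) arrays; bars give the mean and SD, and open points mark groups with no array well above background. Gal, Eno2, Pcsk6, Gstm7, Cacna2d2 and Gpc1 lie higher in all GFP-high arrays, Carnmt1, Ccne2, Mab21l2 and Smoc2 lie lower, and Hcn4 and Isl1 overlap.

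Among genes of the sinus node and atrioventricular canal, 1 of 18 measured members rose (Cacna2d2), 1 fell (Smoc2) and 16 did not pass. Adjusted over the list alone, 4 rose (Cacna2d2, Id2, Rspo3 and Msx2) and 1 fell (Smoc2). The transcriptional regulator Id2 had a log2 difference of 1.495 ± 0.22 (SE, limma adjusted p over all genes 0.0656) and the Wnt agonist gene Rspo3 one of 2.61 ± 0.42 (0.0874). Bmp2, a growth factor of the canal myocardium, had 2.82 ± 1.12 (0.317), Tbx2 0.63 ± 0.23 (0.293) and Tbx3 1.46 ± 0.93 (0.487), with Tbx3 above background on 3 GFP-high and 2 GFP-low arrays. With normexp Id2 passed at 1.29 (0.0478) and Rspo3 at 1.70 (0.0359), and both passed with the common floor (0.0146 and 0.0377), while with normexp Bmp2 had 1.26 and Tbx3 0.67. Hcn4, the main pacemaker channel gene, had -0.65 ± 0.45 (0.518) and Isl1 -0.38 ± 0.55 (0.759). The T-type calcium channel gene Cacna1g had 0.29 ± 0.53, and the connexin genes Gjc1 and Gjd3 had 0.05 ± 0.28 and 0.10 ± 0.42. Shox2 was not well above background on any array, so it was not tested. Positive values were found in 14 of the 18 members. The list median was 0.57 (0.75 within slide 1 and 0.72 within slide 2) with a camera adjusted p of 0.0716. The list passed camera in 5 of 25 alternatives (adjusted p from 0.00997 to 0.236), namely normexp with and without quantile normalisation, the common floor, trend and robust fitting and 1 left-out array. It also passed fry (adjusted p 0.0164), but not camera with an estimated correlation (p = 0.0438, adjusted 0.526). The exact permutation p of its mean was 0.0286, the smallest possible, and 0.137 after adjustment over the lists. Before adjustment 5 of the 24 lists had an exact permutation p under 0.05.

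The ventricular conduction system list, of His-Purkinje genes, had 1 member that fell (Sema3a), none that rose and 12 that did not pass; adjusted over the list alone, 2 rose and 4 fell. Its median was -0.22 and its camera adjusted p 0.222. The mean of the list was lower in GFP-high, at 1.28 ± 0.06 against 1.81 ± 0.17 in GFP-low (SD, n = 4 each). The exact permutation p of this difference was also 0.0286, and 0.137 after adjustment over the lists. The fast-conducting connexin gene Gja5 had -0.22 ± 0.38 (SE) and Nkx2-5 had 0.71 ± 0.33.

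No member of the atrial (15 measured) or ventricular (18 measured) working myocardium lists passed the main test over all genes. Adjusted over the list alone, 1 atrial member rose and 5 fell, and 4 ventricular members fell. Nppa, the natriuretic peptide gene of chamber myocardium, had -0.89 ± 0.23 (SE, limma adjusted p = 0.185), and its second probe gave -0.80. The connexin gene Gja1 had -1.53 ± 0.42 (0.201), Hand1 -1.33 ± 0.28 (0.145), Cited1 -1.61 ± 0.25 (0.0727) and Angpt1 -4.14 ± 0.66 (0.0839), the last measured on 1 GFP-high array; with normexp Angpt1 had -1.41, and with the common floor it passed at -2.03 (0.0470). Cited1 passed with normexp at -1.79 (0.0341) and with the common floor (0.0366). Sln, a regulator of the calcium pump on the atrial list, had the opposite sign at 2.10 ± 0.37 (0.105). Myl2, Nppb, Irx4, Smpx and Hey2 had 0.49, 0.48, 0.16, 0.11 and -0.74, none past the threshold. Camera tests a list against all other genes and gave a downward direction for both (adjusted p = 0.222 each), although the medians were 0.08 and 0.06; the means were -0.43 and -0.30.

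Of the 24 lists, 4 passed camera, all higher in GFP-high. In the BMP and TGF-beta pathway list, 16 of 21 measured members had positive values and the median was 0.41 (0.52 and 0.66 within the slides), with a camera adjusted p of 0.0409, and adjusted p = 0.335 with an estimated correlation (unadjusted 0.0140). No member passed the main test over all genes, though Id2 did in the alternatives above, and 1 rose over the list alone. Among its members, chosen after their values were seen except for Id1, were the pathway's target and inhibitor genes Id1 at 1.103, Id3 at 1.499, Id4 at 1.47, Smad6 at 1.65 and Msx2 at 2.79. These genes lie far above the list median and are not typical of the list. Negative values were found in 5 members, such as Bmp10 at -0.36, also chosen after its value was seen. The list shared Bmp2, Id2 and Msx2 with the sinus node and atrioventricular canal list. Fry, which asks whether members move 1 way on balance, gave an adjusted p of 0.00116.

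Glycolysis genes had positive values in 17 of 18 members with a median of 0.47 (0.55 and 0.32 within the slides) and a camera adjusted p of 0.0409, and adjusted p = 0.848 with an estimated correlation. Eno3 and Gpi1 had 0.64 and 0.54. In the sarcomere list, of contractile apparatus genes, 26 of 29 members were positive with a median of 0.35 (0.46 and 0.24 within the slides) and an adjusted p of 0.0465, and adjusted p = 0.848 with an estimated correlation. Csrp3 had 0.82 and Pdlim5 -0.98. Ribosomal protein genes were positive in 80 of 88 members with a median of 0.27 (0.33 and 0.20 within the slides), an adjusted p of 0.0465, and adjusted p = 0.853 with an estimated correlation; after quantile normalisation the median was 0.02 and camera placed the list below the other genes. No single member of these 3 lists rose or fell, over all genes or over the list alone. None of the 24 lists passed the exact permutation of the list mean after adjustment (lowest adjusted p 0.137), and 8 of the 35 divisions of the arrays into 4 and 4, the real one included, gave 4 or more lists by camera.

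**Figure D2:**
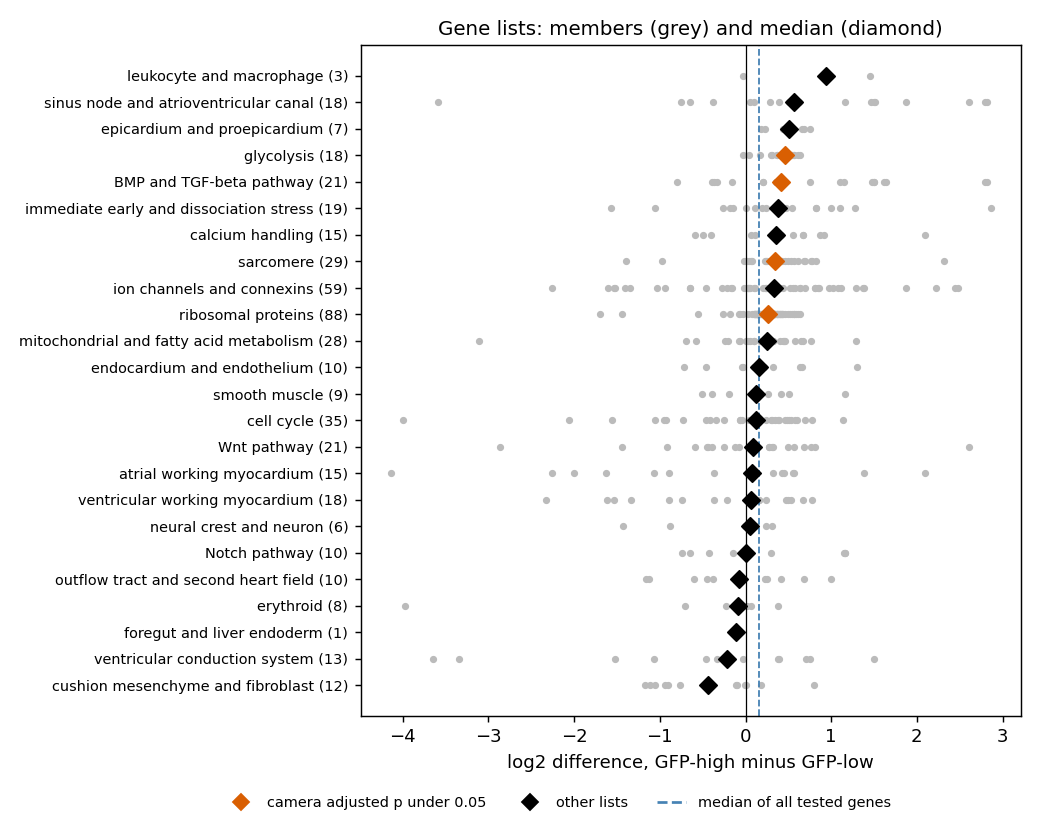
Log2 difference, GFP-high minus GFP-low, of each measured member (grey points) and the median (diamonds) of the 24 gene lists, with the number of measured members in brackets; orange diamonds mark the 4 lists past the camera threshold and the dashed line the median of all tested genes, 0.16. The 4 called lists have medians from 0.27 to 0.47.

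Markers of other cell types gave no list and no member past the threshold in the main test over all genes. The leukocyte list had 3 of 16 members measured and a median of 0.94 (camera adjusted p = 0.222); over the list alone Lyz2 rose, at 1.46 ± 0.24 (SE, limma adjusted p over all genes 0.0951, and 0.0366 with the common floor), a gene with a near-identical copy, Lyz1, while Cd68 had 0.94. The epicardium list had 7 of 15 measured and a median of 0.51 (0.226), the endothelium list 10 of 20 and 0.16 (0.834), the cushion mesenchyme and fibroblast list 12 of 22 and -0.44 (0.222), the erythroid list 8 of 16 and -0.08 (0.388), the neural crest and neuron list 6 of 18 and 0.05 (0.578), the smooth muscle list 9 of 12 and 0.12 (0.867), and the foregut and liver endoderm list 1 of 15 and -0.11 (0.768). Immediate early genes, a sign of tissue dissociation, had a median of 0.38 (0.222) with Btg2 at 1.11, whose 2 other probes gave -0.22 and 0.45, and Nr4a1 at 0.83, and none of its members passed.

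Of the remaining lists, cell cycle had 1 member that fell, Ccne2, none that rose and 34 that did not pass, with a median of 0.12 (camera adjusted p = 0.834). Ion channels and connexins, a list that holds the reporter gene, had 1 member that rose, Cacna2d2, 58 that did not pass and a median of 0.33 (0.222). Calcium handling had a median of 0.36 (0.222), mitochondrial and fatty acid metabolism 0.25 (0.265) with Cox6a2 at 1.29 (limma adjusted p 0.0366 with the common floor), the outflow tract and second heart field -0.08 (0.768), the Notch pathway 0.01 (0.867) with Hes1 at 1.17, and the Wnt pathway 0.08 (0.978) with Sfrp2 at -2.86 ± 0.52 (SE, limma adjusted p = 0.112), or -1.32 with normexp. No member of these 5 lists passed over all genes in the main test.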

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

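The test of probe GC content on the called genes and the splits for genes at an unadjusted p and for genes with separated arrays were chosen after the results were seen; the splits for called genes and lists and the matched random lists were not.

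Of 35 splits of the 8 arrays into 4 and 4, 1 gave as many called genes: the real one, with 18, while the highest other split gave 5. A share of 1 in 35 is the smallest that these splits can give. It makes chance less likely for the count of called genes but does not exclude it. The splits also treat the arrays as unpaired, and with the replicate number as a block 0 genes passed. Only some of the splits part every pair of same-numbered arrays, so under pairing the smallest possible share would be larger. The wider counts leave chance more open. Of the 35 splits, 3 gave as many genes at an unadjusted p under 0.05 (real 1847, highest other 2335). As many genes with separated arrays were given by 3 splits (real 1154, highest other 1482). In both cases the 2 other splits set GFP-high replicates 1, 2 and 4 with 1 GFP-low array against GFP-high replicate 3 and the other GFP-low arrays. The split along the slides gave 0 called genes, and each slide held 2 arrays of each group. Probe GC content was correlated with the log2 difference across genes (Spearman's rho 0.27, and genes are not independent replicates). Removing the trend from each array left the 18 genes at a median of 0.965 of their differences and 12 genes called, 11 of them among the 18. The removal moved the median of all genes only from 0.16 to 0.11. A ratio near 1 was therefore likely for genes selected for large differences, and it cannot decide whether GC content had a part. A difference between the sorted populations remains open as a hypothesis, and each array left out still ended most of the calls, to between 0 and 7 genes.

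The 4 lists past the camera threshold are less secure: 8 of the 35 splits gave as many lists and the highest other split gave 6, so chance cannot be excluded. Of 10000 random lists matched on probe GC content and mean signal, a share of 0.105 had a median as high as the sarcomere list and 0.241 as high as the ribosomal list, consistent with a trend of bright, GC-rich probes in these 2. The share was 0.0148 for the BMP and TGF-beta list, which argues against that trend as its whole cause. For glycolysis the share was 0.0024, but it cannot decide the question. Random lists lack the correlation between glycolysis genes, estimated at 0.57. Signal was also matched in only 4 bins, while the mean signal of glycolysis genes was 6.45 against 0.87 for all genes. After the GC correction the glycolysis median went from 0.47 (quartiles 0.32 and 0.54) to 0.34 (0.18 and 0.55), that of all genes went from 0.16 to 0.11 and the glycolysis call ended (adjusted p 0.0974); what ended it was not tested; the BMP and TGF-beta median went from 0.41 to 0.48 with an adjusted p of 0.0173 (0.00244 to 0.236 over its alternatives). The sorted populations stay among the open explanations for all 4.

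The reporter gene was higher in GFP-high and 14 of 18 members of the sinus node and atrioventricular canal list had positive values. The 4 negative members were Smoc2 (-3.59, called) and, uncalled, Hcn4 (-0.65), Isl1 (-0.38) and Vsnl1 (-0.76), the last named here because it completes the count. Isl1 had -1.51 within slide 1 and 0.75 within slide 2. Why these 4 differed in sign from the other members was not tested.

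Of 206 groups of 4 arrays checked, 15 (7.3%) had 1 array far from the other 3, where 5% were expected by chance. GFP-high replicate 3 stood apart in Gja1 (3.14, others 1.66 to 1.89), Gjc1 (5.21, others 4.45 to 4.57), Nppb (2.78, others 3.43 to 3.46), Hemgn, an erythroid gene (1.06, others -5.40 to -4.64), the mean of the ion channel and connexin list (-0.72, others -0.28 to -0.22) and the correlation of its signal with probe GC content (-0.21, others 0.19 to 0.27). GFP-high replicate 4 stood apart in Egfl7 (1.80, others 0.99 to 1.07) and Cited1 (4.69, others 5.32 to 5.44), and GFP-high replicate 2 in the mean of the ventricular conduction system list (1.20, others 1.30 to 1.31). Among GFP-low arrays, replicate 4 stood apart in Nkx2-5 (3.59, others 2.81 to 2.93) and the mean of the ventricular conduction system list (2.06, others 1.69 to 1.75), replicate 3 in Tbx2 (1.71, others 2.17 to 2.25) and the mean of the smooth muscle list (2.54, others 3.14 to 3.19), replicate 2 in Angpt1 (1.19, others 0.01 to 0.09), and replicate 1 in Lhx1os (-4.42, others -5.14 to -5.02). Lhx1os was not well above background on any GFP-low array, and Hemgn was so on only 1 GFP-high array. Their sizes therefore rest on values near the floor.

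Control spots that entered no comparison also carried signal. Of 10 control probes for the adenoviral E1A gene, 3 were well above background on at least 99.6% of their spots, with median processed signals over the arrays of 688, 249.9 and 316.2 against 5.43 for the negative control. The first 2 were steady, from 613 to 709 and from 237.8 to 276.5, and the last ran from 77.0 to 437.1.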

How the results depend on the processing

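The percentile over detected spots, the common floor, the GC corrections and the threshold of 0.1 were chosen after seeing the data. The count of 18 genes (9 higher, 9 lower) fell to 9 (4, 5) with quantile normalisation, 4 (2, 2) with the median of detected spots and 4 (2, 2) with the percentile over detected spots, 3 (2, 1) without a filter, 11 (10, 1) with the filter on all 8 arrays, 0 with the filter on 1 array (2058 at unadjusted p under 0.05), 11 (3, 8) with the slide block, and 0 at a threshold of 0.01 (1847 at unadjusted p under 0.05). It rose to 38 (20, 18) with array weights, 46 (33, 13) with the common floor and 39 (24, 15) at a threshold of 0.1. It was 20 (14, 6) with normexp, 15 (12, 3) with normexp and quantile normalisation, 19 (14, 5) with trend and robust fitting and 20 (13, 7) with the mean over probes. The genes were partly others. Of the 18, 8 were among the calls with the common floor, 9 with normexp and 8 with normexp and quantile normalisation. Trend and robust fitting kept 12 of them, the mean over probes 13 and array weights all 18. Without 1 array the count was 0 to 7, with 0 to 5 higher and 0 to 5 lower. With the replicate block 0 genes passed (2386 at unadjusted p under 0.05), also with the GC correction (2214). Deviation correlations of same-numbered arrays were 0.12, 0.15, 0.30 and 0.07, so the numbers were not taken to pair the samples. However, 7 of 8 arrays correlated best with their own number, and same-numbered arrays lay side by side on 1 slide. This is a hint from the data only, so pairing stays open, and the counts without this block assume that there is none. Of the 4 called lists, 1 passed with quantile normalisation, the percentile over detected spots, no filter or the GC correction, 2 with the median of detected spots or the GC correction with the replicate block, 1 with either normexp setting or fry, where the sinus node and atrioventricular canal list passed too, 0 with the filters on all 8 or 1 array, the mean over probes or an estimated correlation, 0 to 4 without 1 array, and all 4 with trend and robust fitting or the common floor, where that list made it 5. The ribosomal list turned below other genes, with medians of 0.0212 and 0.0297, under quantile normalisation without and with normexp. The cause was not tested, except that fewer or more genes entered with other filters. Kcne1 kept its direction and an unadjusted limma p under 0.05 in all 25 refits (0.98 to 2.06). None of the 438 refitted values of the 18 genes changed sign and 143 passed. The refits reuse the same arrays, and the 18 genes had separated arrays, so their kept sign was largely fixed by their selection. Only 4 of the 18 passed in most of their refits. Of 55 other named genes, 10 changed sign in at least 1 refit and 25 of 1359 values passed. Whole-series values gave identical results. Signal over background limits the dim genes.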

Other observations

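Bmp2, Msx2 and Rspo3, genes placed with the atrioventricular canal, had large positive differences, while Smoc2, a sinus node gene, was the member of the same list that fell. None of the former passed over all genes in the main test (limma adjusted p 0.317, 0.251 and 0.0874). Their GFP-low signals were near background: Bmp2 was above it on 2 GFP-low arrays, and Msx2 and Rspo3 on 3. With normexp Bmp2 had only 1.26 (0.233), and Rspo3 had 1.70 and passed (0.0359). Among genes of other lists that did not pass over all genes, Sfrp2 had a log2 difference of -2.86 and Sln one of 2.10.

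A hypothesis drawn from these values is that GFP-high, relative to GFP-low, may be enriched more for atrioventricular canal than for sinus node cells at this stage. The values compare the 2 groups and do not give the share of either cell type within GFP-high. The list was divided, after its values were seen, into an atrioventricular canal part (Tbx2, Bmp2, Msx2, Rspo3 and Gjd3, all 5 measured) and a sinus node part (Isl1, Tbx18, Smoc2 and Vsnl1 measured, of 6). The mean log2 difference was 1.79 in the canal part and -1.05 in the sinus node part. With normexp the canal genes Rspo3, Bmp2, Tbx2 and Gjd3 had 1.70, 1.26, 0.51 and -0.004. The means of the parts were not taken with normexp. The difference between the parts was 2.84 (3.46 and 2.23 within the slides), in the same direction on all 4 GFP-high arrays relative to every GFP-low array, with an exact permutation p of 0.0286, the smallest that 70 assignments can give. Smoc2, which with normexp fell by only 0.65, gave most of the sinus node value: without it that part's mean was -0.21 (exact permutation p = 0.543), and the difference between the parts was 2.00 (exact permutation p = 0.0286). Because the division followed the values, these p-values cannot count as independent evidence, and the hypothesis stays open.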
